A study of Mus musculus with 16 samples.

How the data were processed

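Gene expression was measured in brain and liver of 4 male mice heterozygous for HdhQ111, a knock-in allele that places an expanded CAG repeat in the mouse huntingtin gene (Htt), on the C57BL/6J background at 18 weeks of age. Each RNA was hybridised on 2-colour cDNA arrays against a pool of RNA from 4 wildtype males of the same age and tissue. Each mouse and tissue had 2 arrays with the dyes swapped, giving 8 arrays per tissue and 16 in all. The same 4 mutant mice gave both tissues, per the labels. Total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, per the labels' protocols. The scanner, background correction, normalization and spot filters were not given in the sources used here.

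The values analysed were the normalized log2 ratios that the authors deposited for 20794 probes on each array. Base 2 was assumed, since no header states the base. Each array had 19530 to 20584 values, and 210 to 1264 cells were left empty. The deposited columns were not centred. In brain, the arrays with HdhQ111 RNA in Cy5 had medians of -0.064, 0.083, 0.246 and 0.064 for mice 1 to 4, and the arrays with it in Cy3 had medians of -0.128, -0.077, 0.002 and -0.014. In liver, the medians were -0.004, 0.029, 0.023 and 0.036 with the mutant RNA in Cy5 and -0.060, -0.041, -0.057 and -0.041 with it in Cy3. The interquartile range of an array was 0.383 to 1.275. Across all arrays, 1496 values were 16.492 to 16.987 in size, while no other value exceeded 8.297. These look like ratios against a channel set to a floor. All 769 of them on arrays with mutant RNA in Cy5 were positive, and all 727 on arrays with mutant RNA in Cy3 were negative. Without spot intensities, signal over background could not be examined, and the number of arrays limits the precision.

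The direction of the ratios was settled by a rule set before the data were examined. For each dye-swapped pair, the mean of both arrays and their dye difference (the deviation of each array from that mean) were computed. A dye bias belongs to the probe and is shared between tissues. Across 20476 probes, the dye differences of brain and liver correlated (Spearman's rho 0.387) and the pair means did not (rho -0.010). The dye difference was therefore taken as dye bias and the pair mean as the genotype ratio, with all arrays already turned one way. That the sign means HdhQ111 over wildtype is likely, on the basis of the channel order in the labels and the design text, but no header states it. Scale, centring and the overall sign thus stay unknown in part.

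Gene names came from the platform's annotation table, which gave 12771 of the probes exactly 1 symbol, 0 several and the remaining 8023 none. All 12771 matched a current gene through their Entrez number. The names were found to sit 11 rows away from the values, and every gene name printed here uses that offset. The shift was noticed from pituitary genes lying a fixed distance from large brain values. It was then tried over 121 offsets, 60 to each side of 0 and 0 itself, with measures on other genes. Ribosomal, oxidative phosphorylation, proteasome and chaperone probes, which tend to have little scatter, scored 0.290 at offset 11, -0.039 at offset 0 and at most 0.080 elsewhere (262 probes). The liver-minus-brain score of tissue genes was 0.420 at offset 11, 0.168 at 0 and at most 0.241 elsewhere (295 probes). Pairs of probes of one gene at least 50 rows apart correlated by 0.052 on average at offset 11, 0.009 at 0 and at most 0.018 elsewhere (4938 pairs). In each of 4 equal stretches of the array, 11 scored best for the first measure. With the offset, 12760 rows had a name, for 9026 genes. This choice was made after the data were seen, no source states it, and with the names as given no gene list passed in either tissue. No named probe of Htt was analysed here.

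A mouse's value for a probe was the mean of its dye-swapped pair, and required both arrays. Mice were the replicates (n = 4 per tissue), and a probe was tested where at least 3 had a value. The mean log2 ratio was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. The wildtype pool was 1 control sample, so each test leaves out the spread among wildtype mice, and a feature of the pool is shared by all mice of a tissue. Tissues were fitted apart. The liver-minus-brain difference was fitted in limma over the 8 mouse values, and again with the mouse as a block. The block is a valid pairing because both tissues came from the same mice. For a check of the pairing, floor ratios were removed and each mouse's deviation from the mean of its tissue was taken. Spearman's rho between the brain and liver deviations of one mouse was 0.053, -0.013, 0.084 and 0.020 for mice 1 to 4. With the liver of the other mice it averaged -0.021, 0.0094, -0.023 and -0.0099.

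Gene lists were tested with limma's camera for precomputed statistics (cameraPR) on gene-level moderated statistics, with the probes of a gene averaged and the correlation between genes preset to 0.01. Lists with at least 5 measured members were tested, 22 in brain and 28 in liver, with adjustment over the lists of the tissue. The same lists were tested with an estimated correlation and with fry (statmod 1.5.0 served the random-block fits). The brain lists covered striatal projection neurons, synaptic genes, neuropeptides, immediate early genes, oligodendrocytes, astrocytes, microglia, endothelium, choroid plexus and pituitary. The liver lists covered hepatocyte secreted proteins, cytochrome P450 and xenobiotic genes, male-biased and female-biased genes, bile acids, lipid and glucose metabolism, the urea cycle, the acute phase, and Kupffer, stellate, cholangiocyte and pancreas markers. Lists used in both tissues covered chaperones, the proteasome, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, the clock, the interferon and unfolded protein responses, the cell cycle, blood, lymphocytes and genes flanking Htt.

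The lists, the tests, the other settings to be tried and the rule for named genes were all chosen before the data were examined. In each tissue the rule named the probes past the threshold and, where fewer than 20 genes passed, those with the smallest p up to 20 genes. It also named up to 4 genes with the smallest p from each list, and for the tissue difference the 6 smallest p. Alternatives covered array centring and scaling, each dye orientation alone, missing values, array-level fits, trended eBayes, probe averaging, the mouse block and leaving out each mouse. Treating the floor ratios as missing, correcting for residual dye bias or spread, undoing the offset and removing Pomc from the neuropeptides were added after the data were seen.

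Both tests were tested on simulated data made from the measured spread, with 50 changed probes at each of 4 sizes. In brain, limma recovered 0%, 28%, 64% and 92% of probes changed by 0.5, 1, 2 and 4 on the log2 scale among 19325 probes. In liver it recovered 8%, 48%, 92% and 88% among 20127 probes. For the tissue difference it recovered 0%, 28%, 62% and 92% among 19055 probes, with 21 false calls. With the block it recovered 0%, 0%, 34% and 82%, with 3 false calls. The unblocked difference fit is therefore more liberal, and the blocked one recovers less. Camera called 21 of 22 brain lists and 26 of 28 liver lists shifted by 0.2, and called 0 of 440 and 0 of 560 unshifted ones. The simulated genes were independent, so correlation between genes was not covered by that check. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.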

Results

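The data comprised 16 2-colour arrays: 4 HdhQ111 heterozygous mice, 2 tissues and 2 dye-swapped arrays per mouse and tissue, each against a pool of 4 wildtype mice. Per the design text, the comparison asked how the transcriptomes of brain and liver differed between these mice and wildtype mice at 18 weeks. All values are mean log2 ratios, likely HdhQ111 over wildtype, with the SD over mice. Positive values are called higher and negative values lower on that basis. Gene names use the offset of 11 rows between annotation and values. The plot of offset scores shows the basis for it.

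**Figure D1:**
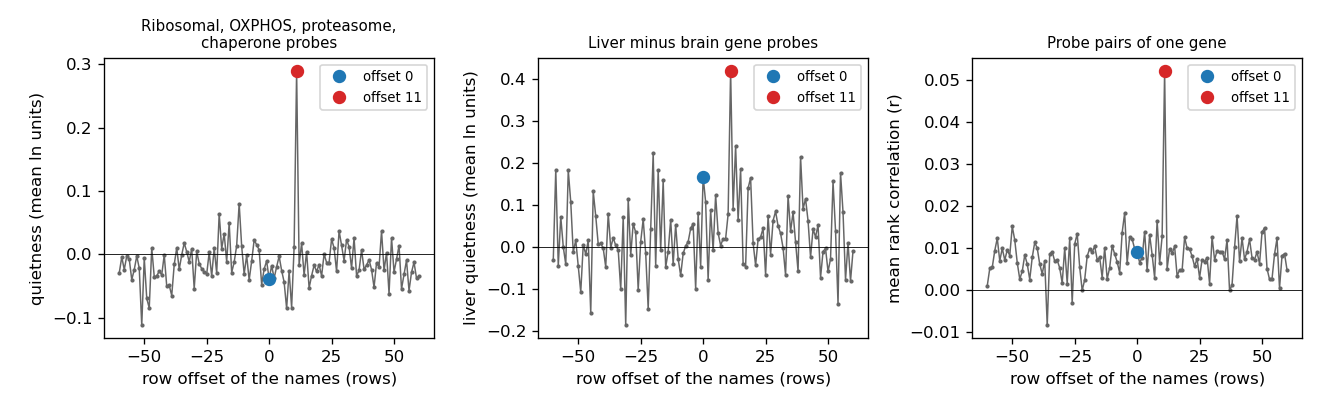
Score of each of 121 row offsets between gene names and values (x axis, rows) for quiet housekeeping probes, for tissue genes and for probe pairs of one gene (y axes, mean score or mean rank correlation). All 3 measures peak at offset 11 (red), with 0.290, 0.420 and 0.052, against -0.039, 0.168 and 0.009 at offset 0 (blue).

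In brain, 4 of the 5 probes with the smallest p, among those with a gene name, belonged to hormone genes of the pituitary, the gland below the hypothalamus, and all 4 were lower. Gh (growth hormone) was at -4.35 ± 1.38 (SD, n = 4 mice) and Prl (prolactin) at -4.28 ± 0.27 (n = 3). Pomc, the precursor of corticotropin, was at -2.75 ± 0.52 (n = 4), and Cga, the common subunit of the glycoprotein hormones, at -1.62 ± 0.49 (n = 4). The list of pituitary markers fell: all 6 measured members were lower, and limma's camera gave an adjusted p of 4.5e-14. With an estimated correlation the adjusted p was 3.0e-04, and with fry it was 0.125. The fry test left out Prl, which had no value in mouse 1. Prl, Pomc, Gh and Cga passed limma's test adjusted over the list alone, while 0 of the 6 passed over all genes. The other members were Tshb (thyrotropin beta) at -0.22 ± 0.17 and Chga at -0.08. These genes led to the row offset, so their list is not independent evidence that the offset holds. In liver, Prl was at 0.24, Pomc at 0.30 and Cga at 0.05. Gh in liver was at -2.14 ± 3.89, with -7.96 in mouse 1 from a floor ratio and -0.40 to -0.06 in the others.

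**Figure D2:**
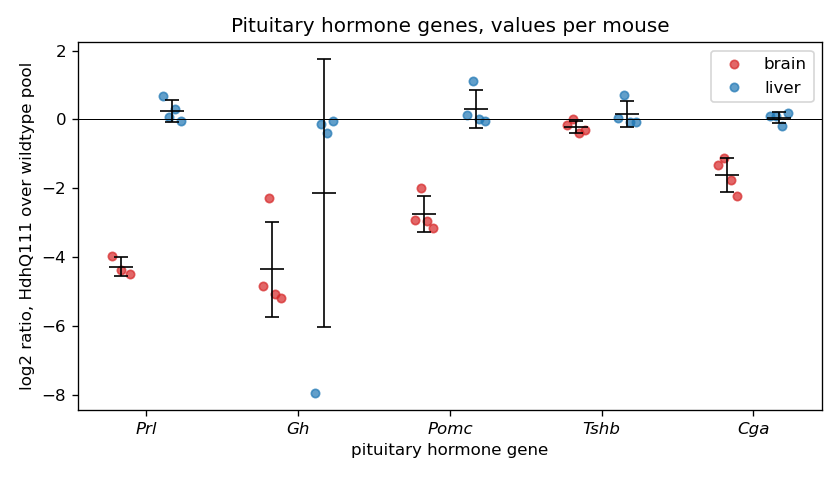
Log2 ratio (y axis) of 5 pituitary hormone genes (x axis) in each mouse, in brain (red) and liver (blue), with the mean and SD as black bars. In brain, Gh, Prl, Pomc and Cga lie below -1 in every mouse with a value, and Tshb averages -0.22.

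No single probe passed in brain. Of 19325 probes tested with limma, 0 had an adjusted p under 0.05, 677 had an unadjusted p under 0.05 (313 higher, 364 lower) and 966.25 would have by chance. The smallest adjusted p was 0.231, for Prl. With the probes of a gene averaged, 0 of 8621 genes passed, 269 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0549. Under the alternative settings at most 3 probes passed. Beyond the pituitary genes, the 20 genes with the smallest p, none of which passed, included the lens crystallin Crybb2 (-1.90 ± 0.34) in the row after Prl, and Cga lay in the row before Prl. Nr5a1, a nuclear receptor of the pituitary, hypothalamus and steroid-producing glands, was at -1.19. Lower values were also found for Arhgap33 (-1.21), Padi2 (-1.12), Aste1 (-1.02), Abra (-0.96), Nln (-0.90), Akr1cl (-0.85), Clec1b (-0.79) and Epb41l4a (-0.78). Higher values were found for Oaz3 (1.53), Lin7b (1.10), the histone demethylase Kdm1a (1.05), Spata6 (0.97), the organic solute transporter subunit Slc51a (0.88) and arginase Arg1 (0.62).

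A pair of housekeeping lists passed camera in the higher direction in brain, both with small shifts. Of 62 oxidative phosphorylation genes, 55 were higher, with a median of 0.10 (adjusted p = 0.00201 by camera, but adjusted p = 0.929 with an estimated correlation). Ndufc2 was at 0.23 ± 0.16, Atp5l at 0.23 ± 0.21 and Atp5k at 0.28 ± 0.30. Of 54 cytosolic ribosomal proteins, 44 were higher, with a median of 0.094 (adjusted p = 0.0412 by camera, but adjusted p = 0.929 with an estimated correlation), including Rps16 at 0.32 ± 0.26 and Rps9 at 0.30 ± 0.23. With fry both lists had an adjusted p of 0.958. On the arrays with HdhQ111 RNA in Cy3 the direction turned, with an adjusted p of 0.263 for oxidative phosphorylation and 0.0127, lower, for the ribosomal proteins, and Ndufc2 and Rps16 were below 0. Without mouse 3 the adjusted p values were 0.555 and 0.623. In both lists 0 members passed, adjusted over the list alone or over all genes.

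The other 19 brain lists did not pass. Striatal projection neuron genes, the cells most affected in Huntington's disease, had a median of 0.0021 over 24 genes (adjusted p = 0.837), with Penk (enkephalin) at -0.24 ± 0.06 and Actn2 at -0.36 ± 0.32. Synaptic genes had an adjusted p of 0.892, with Shank3 at 0.36 ± 0.29. Neuropeptides had 0.259, and their 1 member past the test adjusted over the list alone was Pomc. Immediate early genes had 0.763, with Egr1 at -0.46 ± 0.24. Of the cell type markers, microglia had a median of 0.13 and an adjusted p of 0.112, with C1qa at 0.32 ± 0.16. Astrocytes had an adjusted p of 0.837, with 8 genes higher and 6 lower. S100b was at 0.75 ± 0.43, but Slc1a2 was at -0.22 ± 0.19, Fgfr3 at -0.15 ± 0.12 and Aqp4 at -0.27 ± 0.47. Endothelium had an adjusted p of 0.837. Oligodendrocytes had 0.780, with Mag at 0.10, choroid plexus and ependyma 0.567, erythroid and blood genes 0.763, and lymphocytes 0.892. Adjusted p values were 0.112 for the proteasome, 0.763 for chaperones, 0.160 for cholesterol synthesis (Ebp 0.58 ± 0.45) and 0.160 for the clock (Per2 -0.33 ± 0.20). They were 0.763 for interferon response genes (H2-K1 0.71 ± 0.52), 0.837 for the unfolded protein response, 0.667 for the cell cycle and 0.763 for genes flanking Htt (Stk32b -0.64 ± 0.28, n = 3). Several of these lists, among them the striatal, synaptic and astrocyte genes, had a test direction opposite to the sign of their median. Penk was above 0 on the Cy5 arrays alone, and Mag below 0 on the Cy3 arrays alone.

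In liver, 11 of the 28 lists passed camera, all in the lower direction and by small amounts, and 1 of them passed with an estimated correlation. Male-biased liver genes, which are expressed more in males under pulsatile growth hormone, fell: 9 of 10 were lower, with a median of -0.38 (camera adjusted p = 2.2e-05). Among them Cyp7b1, an oxysterol hydroxylase, was at -0.475 ± 0.12, Nudt7 at -0.48 ± 0.14 and Selenbp2 at -0.45 ± 0.24. These 3 genes passed limma's test adjusted over the list alone, and 0 passed over all genes. It was the one liver list past the threshold with an estimated correlation (adjusted p = 4.0e-05) and with fry (8.2e-04). Its estimated correlation was 0, below the preset 0.01, so that camera test was no stricter for it. Female-biased liver genes had a median of -0.016 over 8 genes (adjusted p = 0.962). On the arrays with HdhQ111 RNA in Cy5 alone the male-biased list did not pass (adjusted p = 0.607), and on the Cy3 arrays it did (0.00153).

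Oxidative phosphorylation genes fell in liver, with 57 of 62 lower, a median of -0.18 and an adjusted p of 6.2e-09 by camera, but adjusted p = 0.366 with an estimated correlation. Sdhb was at -0.32 ± 0.16 and Cyc1 at -0.29 ± 0.14. Cytosolic ribosomal proteins fell, with 48 of 54 lower and a median of -0.17 (2.5e-08), including Rpl8 at -0.46 ± 0.16 and Rps13 at -0.26 ± 0.03 (adjusted p = 0.342 with an estimated correlation). Chaperones fell, with 24 of 30 lower (adjusted p = 0.00170), Cct5 at -0.34 ± 0.13 and Hspe1 at -0.30 ± 0.17 (adjusted p = 0.342 with an estimated correlation). Interferon response genes fell, with 17 of 20 lower (adjusted p = 0.00334). They included Tap1 at -0.61 ± 0.41 and Irf9 at -0.46 ± 0.32, while Rsad2 was at 0.29 ± 0.08 (adjusted p = 0.107 with an estimated correlation).

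Lists of hepatocyte products and enzymes fell as well. Hepatocyte secreted proteins had 19 of 20 genes lower, with a median of -0.19 (adjusted p = 2.2e-05), including Serpina1b at -0.29 ± 0.10 and prothrombin, F2, at -0.28 ± 0.18. With an estimated correlation the adjusted p was 0.342. Cytochrome P450 and xenobiotic genes had 21 of 22 lower and a median of -0.26 (adjusted p = 2.2e-05), with Gsta3 at -0.38 ± 0.18 and Cyp2d9, also a male-biased gene, at -0.36 ± 0.22. With an estimated correlation the adjusted p was 0.366. Fatty acid oxidation genes and targets of PPAR alpha had 21 of 25 lower (adjusted p = 2.9e-04), among them Creb3l3 at -0.35 ± 0.14 and Hadha at -0.23 ± 0.04. With an estimated correlation the adjusted p was 0.342. The urea cycle and amino acid catabolism list had 19 of 21 lower (adjusted p = 0.00123), with argininosuccinate lyase, Asl, at -0.36 ± 0.21 (adjusted p = 0.440 with an estimated correlation). Cholesterol synthesis had 10 of 12 lower (adjusted p = 0.0375), with Fdps at -0.66 ± 0.37 and Pmvk at 0.36 ± 0.38 (adjusted p = 0.342 with an estimated correlation). Fatty acid and triglyceride synthesis had 22 of 27 lower (adjusted p = 0.0442), with Agpat2 at -0.19 ± 0.08 and Fasn at -0.50 ± 0.67 (adjusted p = 0.342 with an estimated correlation).

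In these 10 lists 0 members passed, adjusted over the list alone or over all genes. On the arrays with HdhQ111 RNA in Cy5 alone, 0 of the 28 liver lists passed, and 5 of the 11 had a median below 0. On those with it in Cy3, 9 of the 11 passed lower, and all 11 medians were below 0. Serpina1b and Pmvk had the opposite sign on the Cy5 arrays alone.

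**Figure D3:**
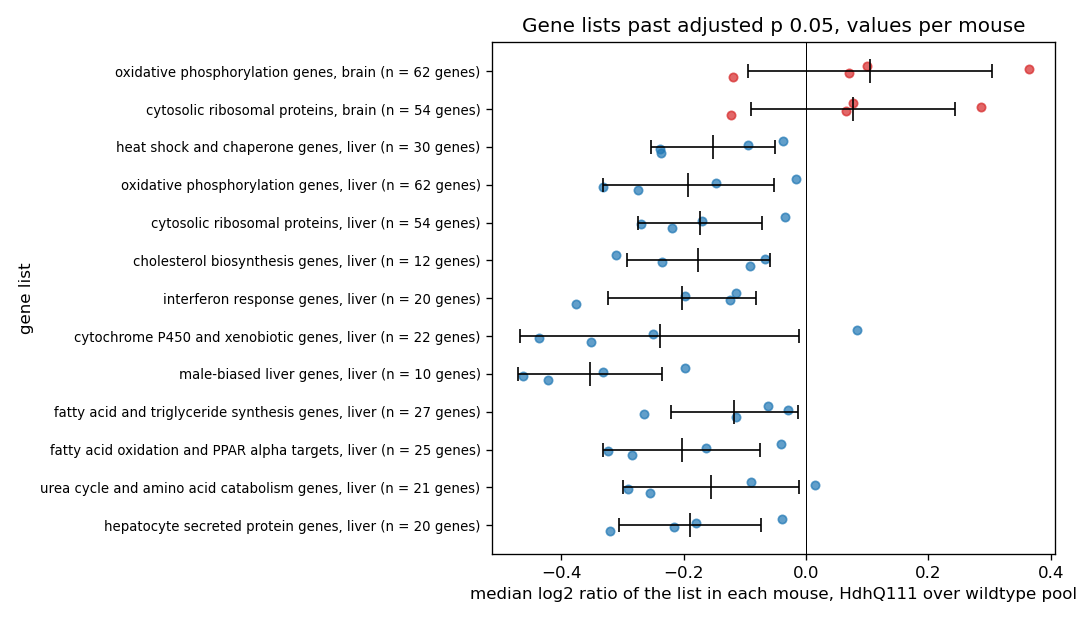
Median log2 ratio of each gene list past adjusted p 0.05 (x axis) in each of the 4 mice (points), in brain (red) and liver (blue), with the mean and SD over mice as black bars and the pituitary list left out. The 11 liver lists average below 0 and the 2 brain lists above 0, and the brain lists turn on the arrays with HdhQ111 RNA in Cy3.

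No single probe passed in liver. Of 20127 probes tested with limma, 0 had an adjusted p under 0.05, and 1409 had an unadjusted p under 0.05 (580 higher, 829 lower), against 1006.35 by chance. The smallest adjusted p was 0.636. With probes averaged, 0 of 8828 genes passed and 671 had an unadjusted p under 0.05. Among the 20 genes with the smallest p, none of which passed, lower values included Casp6 (-0.93, n = 3), Frmd4a (-0.83, n = 3), Alas1, the first enzyme of heme synthesis (-0.57), and the methyltransferase Inmt (-0.56). They also included Nat8f2 (-0.53), Selenbp1 (-0.50), Cyp7b1 (-0.475), Nudt7 (-0.48), the carboxylesterase Ces3b (-0.47) and Mtss1 (-0.41). Higher values were found for Amph (0.89), Npb (0.70), Knstrn (0.70), Mvb12b (0.60), Mdp1 (0.55), Stac3 (0.53), Nudt13 (0.50), Gpsm3 (0.48), the deacetylase Sirt7 (0.48) and Gtsf1l (0.45). On the Cy5 arrays alone the values of Casp6, Knstrn, Mvb12b, Mdp1 and Nudt13 had the opposite sign. The Casp6 value there, 3.79, may rest on a floor ratio in mouse 1, which had no pair mean for Casp6.

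The remaining 17 liver lists did not pass. Bile acid genes had an adjusted p of 0.114, with 1 member, Cyp7b1, past the test adjusted over the list alone. Glucose metabolism had 0.350 and acute phase and complement genes 0.840, with Hamp (hepcidin) at -0.59 ± 0.63. Clock genes had 0.857, with 7 higher and 7 lower. Among them Per2 was at -0.40 ± 0.23, Tef at -0.39 ± 0.27, Per3 at -0.31 ± 0.20 and Bhlhe41 at 0.23 ± 0.12. Kupffer cell markers had 0.7005, stellate cell markers 0.840 (Des -0.31 ± 0.09), cholangiocyte markers 0.840 (Cldn4 0.70 ± 0.35, n = 3, but below 0 on the Cy3 arrays alone) and pancreas markers 0.625. Endothelial markers had 0.703, blood genes 0.350, lymphocyte genes 0.857, immediate early genes 0.350, the proteasome 0.231, the unfolded protein response 0.1497, the cell cycle 0.989 and genes flanking Htt 0.857.

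The tissues were compared directly through the liver-minus-brain difference of the log2 ratios. Prl had the smallest p, with a difference of 4.52 ± 0.23 (SE). It was the 1 of 19055 probes that passed limma's test (adjusted p = 0.00238), while 1233 had an unadjusted p under 0.05. With the mouse as a block, 1 probe passed, but it was Pomc (3.05, adjusted p = 0.0435), and Prl had an adjusted p of 0.168. Prl was at -4.28 in brain and 0.24 in liver, and Pomc at -2.75 and 0.30. Both differences thus rest on the brain values, and signal over background in liver was not examined. Without mouse 3 or without mouse 4, 0 probes passed. The other named genes, which did not pass, were Crybb2 (1.70), Cga (1.67), Arhgap33 (1.35) and Slc51a (-1.01).

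Of the 14 lists used in both tissues, 6 differed by camera, all lower in liver than in brain, and 6 passed with the block too. The median difference was -0.29 for oxidative phosphorylation (adjusted p = 1.9e-10), -0.23 for ribosomal proteins (6.0e-09) and -0.25 for chaperones (0.00850). It was -0.25 for interferon response genes (0.00850), -0.20 for the proteasome (0.0285) and -0.33 for cholesterol synthesis (0.0285). An estimated correlation was not applied to these differences, and the preset one is small beside those estimated within tissues. The mean log2 ratios of brain and liver did not correlate across 19055 probes, with Pearson's r 0.0049 and Spearman's rho -0.012, where probes are not independent replicates. Within one dye orientation rho was 0.296 (Cy5) and 0.327 (Cy3). A single orientation leaves each probe's dye bias in the value, and the dye differences of brain and liver correlated by rho 0.387.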

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

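Chosen only after the result was seen were the tests for pituitary tissue in the pool, for 3 single hypothalamic genes, for the male-biased genes against other liver genes and after dye correction, and the corrections for dye bias and spread. The same holds for 1 added condition on the growth hormone test, described beside its value. The dye correction of the male-biased genes replaced an earlier test by dye orientation, which had left dye bias open: their mouse medians averaged -0.054 (SE 0.059) on the Cy5 arrays and -0.54 (SE 0.084) on the Cy3 arrays. A single orientation holds each probe's own dye bias, which averaging the 2 orientations reduces, and the correction removes a linear trend only.

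In brain, 4 of the 5 hormone genes measured for the pituitary (Prl, Gh, Pomc and Cga) lay below -1 in every mouse with a value, and Tshb averaged -0.22; Cga lay in the row next to Prl, as did the lens gene Crybb2 (-1.90), so its value may not be independent of Prl. Pituitary tissue in the wildtype brain pool is a candidate explanation that was not tested independently, since those 4 genes prompted it. A set of 6 further pituitary-enriched genes (Dlk1, Epcam, Cdh1, Gal, Esr1 and Crhr1) had a median of -0.14, from -0.53 to 0.062. Their expression in brain itself was not examined, so this median does not decide on that explanation. Less hypothalamus in the mutant samples needed a median below -1 over 7 hypothalamic neuropeptide genes. Their median was 0.0904 (SE 0.16 over genes, Npy measured in 1 mouse only), so that condition was not met. Npy, Sst, Tac1 and Nts are also widely expressed elsewhere. Of the others, Avp was at 0.20 ± 0.38, Trh at 0.040 ± 0.40 and Gnrh1 at 0.090 ± 0.54. Nr5a1, of hypothalamus and pituitary, was at -1.19. Avp, Trh and Gnrh1 gave values in liver too (-0.013, 0.018 and 0.31). Signal over background was not examined, and a spot without signal can also lie near 0. These genes therefore do not decide on less hypothalamus. Lower growth hormone output stays open: the mouse medians of Igfals, Socs2 and Cish in liver averaged -0.10 (SE 0.026 over mice), which met the condition set beforehand. However, 85 genes of the hepatocyte secreted, P450, urea cycle and fatty acid oxidation lists had a median over genes of -0.19. By that measure Igfals, Socs2 and Cish had -0.087. The added condition that the shift exceed that of the 85 genes was not met by either value. A genotype effect on the pituitary cannot be told apart from the pool, because all 4 mice were set against the same pool.

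In liver, 11 lists were lower by camera, but only 1 of them passed with an estimated correlation, which was 0 for that list. On the Cy5 arrays alone 0 passed, and 5 of the 11 medians were below 0. By camera, 9 of the 11 passed after correction for a trend on spread, which argues against that trend as the whole cause of those camera calls. The spread was taken over the arrays of both orientations, so it also holds dye bias. Spot intensities were not available, so a trend on signal itself was not tested. After correction for a linear trend on the dye bias left in the averaged orientations, 9 passed too. This does not decide on dye bias, since 1 linear trend over all probes may remove too little of it. The liver pair means correlated with the dye bias of the other 3 mice by rho -0.175, -0.172, -0.219 and -0.029 for mice 1 to 4. Both corrections ended the calls of cholesterol synthesis (median -0.17 before, -0.16 and -0.15 after, SD 0.12 over mice before) and of fatty acid and triglyceride synthesis (-0.14 before, -0.12 after both, SD 0.10), whose adjusted p values of 0.0375 and 0.0442 were near the threshold at the start. A chance feature of the wildtype pool cannot be told apart from genotype, since either could give the mean correlation between mice of rho 0.110. Dye bias left in the pair means could add to it, since the liver dye differences correlated between mice by a mean rho of 0.373. The 8 sign patterns of the 4 mice are too few for a share under 0.05: the real signs gave 11 lists and 1409 probes at an unadjusted p under 0.05, reached by 1 pattern each, and the highest other pattern 7 and 847.

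The male-biased liver genes had a median of -0.38, at percentile 0 of 10000 random lists of 10 genes (5th percentile -0.26). The draws came from the 85 genes of the hepatocyte secreted, P450, urea cycle and fatty acid oxidation lists, male-biased genes left out. That argues against a mere part of the shift of those lists. Those draws ignore correlation between genes and were made after the list's median was known. After correction for the dye bias left in the averaged orientations, the mouse medians of the list averaged -0.31 (SE 0.047), against -0.35 (SE 0.059) before. Dye bias stays open, since 1 linear trend over all probes may remove too little of it. The mouse medians averaged -0.054 (SE 0.059) on the Cy5 arrays alone and -0.54 (SE 0.084) on the Cy3 arrays alone. A biological candidate is weaker male-type growth hormone signalling, but the wildtype pool could give this median too, and female-biased genes had a median of -0.016. It was not tested beyond the growth hormone genes above, no pituitary was sampled, and deciding it would need livers and pituitaries of single wildtype and mutant mice.

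Prl differed between liver and brain by 4.52, past limma's threshold without the mouse block (adjusted p = 0.00238) but not with it (0.168). That difference rests on the brain value of -4.28, with 0.24 in liver. The median difference was -0.25 for heat shock and chaperone genes, -0.20 for proteasome genes, -0.29 for oxidative phosphorylation, -0.23 for ribosomal proteins, -0.33 for cholesterol synthesis and -0.25 for interferon response genes. Of the 35 splits of the 8 mouse values, 1 gave as many as 6 lists (highest other 5). As many as 1233 probes at an unadjusted p under 0.05 came from 2 splits (highest other 1676), and as many as 1 probe past the adjusted threshold from 3 (highest other 3), so chance was not excluded for the probe counts. Among the 8 splits that part the tissues of every mouse, the real one gave 6 lists and 1233 probes, and the highest other 4 and 873. Brain and liver came from the same mice, and these 8 are too few for a share under 0.05, so the 35 splits do not exclude chance for the lists either. In brain alone, 5 of 8 sign patterns gave as many as 677 probes (highest other 1062) and 4 gave as many as 3 lists (highest other 5), and 8 patterns are too few for a share under 0.05.

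Of 263 groups of values examined, 12 held a value far from the others, and chance gives about 1 in 20. Gh in brain was -2.29 in mouse 2 and -5.20 to -4.86 in the others. Hlf in brain was -3.60 in mouse 3 and -0.54 to -0.43 in the others. Nr1d2 in brain was -0.022 in mouse 2 and -0.29 to -0.27 in the others. Gsn in brain was -0.22 in mouse 1 and 0.23 to 0.26 in the others. Lyz2 in brain was -0.068 in mouse 4 and 0.18 to 0.20 in the others. Slc4a1 in brain was -8.58 in mouse 2, from a floor ratio, and -0.85 to 0.25 in the others. Cd3e in brain was -0.64 in mouse 3 and 0.92 to 1.05 in the others, and Cd3g was 0.94 in mouse 2 and 0.022 to 0.070 in the others. Sel1l in brain was 0.028 in mouse 4 and -0.21 to -0.18 in the others. Cyp4a14 in liver was 0.74 in mouse 4 and -0.55 to -0.36 in the others, and Slc27a2 was -0.005 in mouse 4 and -0.47 to -0.41 in the others. The median of lymphocyte genes in liver was -0.074 in mouse 3 and 0.010 to 0.016 in the others.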

How the results depend on the processing

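Undoing the row offset, the corrections for dye bias and spread, treating floor ratios as missing and removing Pomc from the neuropeptides were chosen after the data were seen, and all other settings were planned. No probe passed in liver under any setting, with limma throughout. In brain, 3 probes passed with both tissues in one fit, 3 with arrays fitted with a dye term, 3 without the probes with the largest dye difference, 2 on the Cy5 arrays alone, 1 with single arrays allowed, and 0 to 1 without each mouse (1 without mouse 2). For the tissue difference the mouse block gave 1 probe, and this was Pomc in place of Prl; block or no block, 6 lists passed. The difference had 0 probes with scaled arrays, 0 with complete probes, 0 with trended and robust eBayes, 2 with the array fit, 2 without the probes of large dye difference, 2 with floor ratios as missing, and 0 to 1 without each mouse. Brain lists past the threshold numbered 1 with an estimated correlation, 0 with fry, 0 with names as given, and 1 to 4 without each mouse (1 without mouse 3). Liver lists numbered 1 with an estimated correlation, 1 with fry, 0 with names as given, 0 on the Cy5 arrays alone and 9 to 11 without each mouse. The pituitary list passed under 16 of its 18 alternatives, the brain oxidative phosphorylation list under 13 and the brain ribosomal list under 6. In liver, the male-biased list passed under 15 of 17 alternatives and fatty acid and triglyceride synthesis under 6. Without Pomc the neuropeptides had an adjusted p of 0.837. The correlation of brain and liver values, over the probes with enough mice in each setting, was 0.295 on the Cy5 arrays and 0.327 on the Cy3 arrays. A single orientation leaves each probe's dye bias in these values. Without each mouse the correlation was -0.035 to 0.017. No named Htt probe was analysed here, so its alternatives were not run. Spot signal over background was not analysed here, so its limit on weak probes is unknown.

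With names as given, the direction turned for brain ribosomal proteins and pituitary markers (adjusted p = 0.983 each) and for liver cholesterol synthesis and fatty acid synthesis (0.877 each), ribosomal proteins (0.920), interferon response and urea cycle genes (0.993 each). On the Cy5 arrays it turned in liver for ribosomal proteins and P450 genes (0.681 each) and for fatty acid synthesis, urea cycle and hepatocyte secreted proteins (0.607 each). On the Cy3 arrays it turned in brain for oxidative phosphorylation (0.263) and ribosomal proteins (0.0127). The cause was not tested; a single orientation leaves each probe's dye bias in the value.

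Of the named genes, 51 changed sign on the Cy5 arrays, 30 on the Cy3 arrays, 2 in the array fit and 2 without mouse 2. None had passed in a single tissue. On the Cy5 arrays the log2 ratios in liver were Aass 0.10, Bhlhe41 -0.011, Bst2 0.089, Bub1b -0.047, Calr 0.051, Casp6 3.79, Ccl6 0.12, Cd3e 0.41, Cd4 0.17, Cd74 0.0022, Cldn7 -0.17, Clps 0.015, Cpa1 -0.13, Ctrl -0.02, Cyp4a14 0.11, Dcn 0.093, Eng -0.11, Fech 0.15, Fetub 0.14, Fgfr4 0.15, Hba-a1 0.23, Hgd 0.05, Hgfac 0.10, Hpd 0.017, Knstrn -0.79, Krt18 0.073, Lrpap1 0.043, Mcm5 0.029, Mdp1 -0.0015, Mvb12b -0.81, Ndufa1 0.045, Nudt13 -0.10, Pmvk -0.14, Psmd4 0.0897, Rplp2 0.034, S100a8 -1.02, Serpina1b 0.14, Tat 0.18, Tff2 0.0067, Timp2 -0.36 and Tmem128 0.0063. In brain they were Grin2b 0.011, H2-Eb1 0.47, Hlf 0.18, Mcm2 0.20, Ngp -0.33, Nr1d2 0.36, Penk 0.20, Sel1l 0.041, Slc1a2 0.11 and Ttr 0.16. On the Cy3 arrays they were, in brain, Avp -0.0103, Cd3g -0.022, Chac1 -0.14, Folr1 0.62, Gria3 -0.015, Ifi35 0.083, Il7r -0.18, Irf7 -0.12, Itgam -0.27, Itpka -0.36, Laptm5 -0.70, Lyz2 -0.12, Mag -0.20, Mal -0.043, Mrfap1 0.087, Ndufc2 -0.14, Nr4a1 -0.045, Pdia4 -0.13, Psmd14 -0.20, Rps16 -0.10, Rps29 -0.18, S100a8 0.37, Sqle -0.058, Tmem72 -0.39, Vamp2 -0.083 and Vwf -1.25. In liver they were Acot3 0.18, Cd5l 0.72, Cldn4 -0.22 and Pcx 0.40. The array fit gave Acot3 0.071 and Casp6 0.9999. Both Casp6 values, 3.79 and 0.9999, may rest on a floor ratio in mouse 1, which had no pair mean for Casp6. Without mouse 2, Cldn7 in liver was -0.0057 and Tmem72 in brain was -0.11, and the ranges without each mouse were -0.0057 to 0.59 and -0.11 to 0.71.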

Other observations

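No test in this part was chosen after its result was seen, and the correlations between mice and the shared signs are descriptive. Across probes, Spearman's rho between mice averaged 0.110 in liver (0.033 to 0.211 over 6 pairs) and 6.2e-04 in brain (-0.132 to 0.093). All 4 mice shared a sign at 20.6% of 18286 liver probes, against 12.8% for independent mice, and at 10.8% of 16607 brain probes, against 11.6%. All mice of a tissue share 1 wildtype pool, so a feature of the pool is part of these values. Dye bias left in the pair means may be part of them as well.

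Genes flanking Htt on mouse chromosome 5, which a knock-in strain can carry from another background, had medians of -0.009 in brain and -0.048 in liver over 37 genes. Neither passed camera, with adjusted p values of 0.763 and 0.857. The genes with the smallest p were Stk32b at -0.64 in brain and Nelfa at 0.35 in liver.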
